A study of Mus musculus with 2 samples.

How the data were processed

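ChIP-seq measured COUP-TFI enrichment in crosslinked neural retina of wild-type mouse embryos at embryonic day 14.5, with 1 antibody library and 1 input library, each prepared with the EZ ChIP kit per the labels' protocols. The submitters' processing notes name FastQC, Bowtie2 2.3.1 and HOMER 4.2 and the genome build mm10. Starting from the authors' peak list, the work here did not use reads or coverage tracks.

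Per the file headers, the authors called peaks with HOMER findPeaks in its transcription factor mode, from 1 ChIP tag directory against 1 input directory. Peaks were 251 bp wide, the fragment length was 158 bp, at most 1 tag was counted per position, and the false discovery rate of 0.001 set a minimum of 10 tags. Per the file headers, a peak also had to reach 4-fold over input and 4-fold over the surrounding 10 kb, each with a Poisson p of at most 1e-04. The mean density was 0.003225 tags per bp, which gives 0.809 tags per peak by chance, so that the counts of 10 to 21 tags behind single peaks carry wide counting intervals.

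The deposited values came in several units. Tag counts per peak are whole numbers of ChIP tags, deposited as counts with no scaling. In 21 peaks, among them the Zfp978 peak of 14 tags, the count differs beyond rounding from the one that the scaled tags give. The deposited signal values are tags scaled to a library of 10000000 tags and input tags scaled to the depth of the ChIP library, with a lower bound of 1.9 tags per peak at which 713 peaks sit. The deposited fold ratios divide ChIP tags by scaled input tags or by the density of the surrounding 10 kb. That density also has a lower bound, at which 473 peaks sit, and there the fold over the local region follows the ChIP tags alone. The deposited p-values are Poisson p-values against input and against the local region, with no adjustment. The focus ratio is a fraction given by the authors' caller and was not used to choose peaks. The caller score deposited by the authors is not defined further in the file, and its whole numbers run from 10 to 17. It was used here only to rank peaks, and 591 of the 754 peaks (78.4%) share the lowest score. Folds, scores and p-values of single peaks in the text are the authors' own.

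Gene positions came from a RefSeq gene table of the assembly GRCm38, of which mm10 is another name. Of its 49997 genes, 402 on scaffolds, on the mitochondrial chromosome or without a placed position were left out, which left 49595, of which 21774 are protein-coding. The table gives the start and end of each gene but neither strand nor exons, and no genome sequence was used here. Promoters, exons, introns and transcription start sites were thus not told apart. The test planned around start sites was run on the distance from a peak centre to either end of a gene, and the planned classes became gene bodies and the space outside them. The planned tests of 24 sequence motifs, those of peak height by motif and those with random positions matched on base composition were not run.

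The gene of a peak was the nearest by distance from the peak centre to the gene body, and where genes overlap at the peak all of them counted. All 561 genes of the 18 lists were found in the table. The lists, the main tests, most alternatives and the rule for named genes were fixed before the data were examined. That plan did not name the count over the 14 lists together or the tests over the 19 autosomes together. It also assigned peaks by the nearest start site, which the distance to the gene body replaced here. The rule named Nr2f1, then the 10 peaks with the highest caller score, then the best peak of each list and further listed peaks by score up to 20 genes. Listed genes without a peak were named only among the first 3 of their list, and some of these are not reported here. Peaks of equal score were ranked by their scaled tags and then by their fold over the local region, also where the 377 higher-scoring peaks were chosen. The lowest score, 10, began at rank 164, so most of the 377 entered by this rule for ties.

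Peaks were compared with 10000 seeded random placements. Each peak kept its width and chromosome and could fall anywhere between the first and the last annotated gene. Two-sided p-values from these placements are called permutation p below, although positions were drawn evenly at random and nothing was exchanged. These p-values were doubled from the smaller tail, and the smallest possible is 2.00e-04. They were adjusted by the Benjamini-Hochberg method over the 18 lists and over the 4 classes. Chromosome counts were tested with two-sided exact binomial tests against the share of annotated genes, adjusted over 20 chromosomes with Y left out. Shares carry 95% exact binomial intervals and tag counts 95% exact Poisson intervals. Peaks are not biological replicates, so every p-value describes the spread of this 1 list over the genome. Alternatives used the higher-scoring peaks, a stricter fold over input, other distances, protein-coding genes only, nearby peaks merged, each gene counted once, and other expected shares per chromosome. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 drew the figures.

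The placement test was tested on simulated data. Of 754 randomly placed peaks, some were moved to where a gene of the axon guidance list is nearest. A 3-fold excess was then called in 100% of 100 simulations and a 2-fold excess in 16%. For the eye field list, whose expected count is 0.503, a 5-fold excess was called in 6%, so that only large effects could pass for the short lists. A gene body share raised by 5 percentage points was called in 81% of 100 simulations, by 10 points in 100%, and an unchanged share in 8%.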

Results

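The data are a list of mouse genome regions enriched by ChIP with an antibody to COUP-TFI in the developing eye. COUP-TFI, encoded by the gene Nr2f1, is an orphan nuclear receptor that represses or activates transcription in the developing brain and eye. Chromatin came from the neural retina of wild-type E14.5 embryos, a stage when retinal progenitors divide and the first ganglion cells, horizontal cells and cones have been born. The tissue was crosslinked, and DNA was recovered in 1 library with an antibody to COUP-TFI and in 1 input library without antibody. The ChIP library held 7371400 tags, while the depth of the input library was not given in the sources used here. There was no replicate of either library, so no difference between libraries has a replicate check, and intervals on tag counts cover counting error only. These intervals treat each tag as an independent count and are too narrow where tags come in pairs. Of the peaks with 11 to 16 tags, 332 had an even count and 156 an odd one.

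The first question was where COUP-TFI was enriched over input. The authors' peak list held 754 peaks, each 251 bp wide, on the 19 autosomes and the X chromosome. The peaks were low: the median was 12 tags, the range 10 to 21, and 579 of the 754 (76.8%) had at most 12 tags, against the 10 tags that the caller required. Together they held 8821 tags per the file header, 0.12% of the library, while the counts listed per peak add up to 8845. The authors' fold over input ran from 4.07 to 9.69 with a median of 5.92. In 713 peaks (94.6%) the scaled input stood at its lowest value, 1.9 tags, so that in these peaks the fold followed the ChIP tags alone. The caller had begun with 1283 regions, of which 522 failed against input and 7 failed against the surrounding 10 kb.

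**Figure D1:**
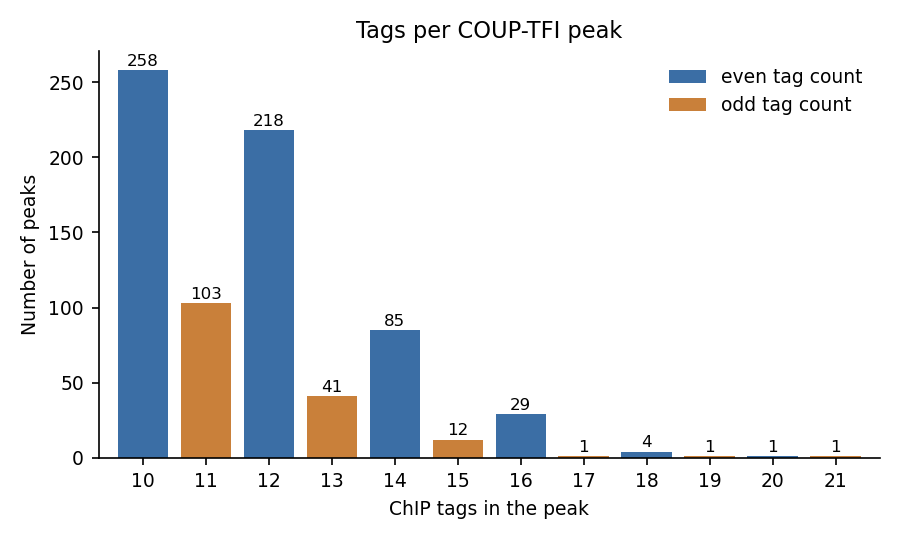
Number of COUP-TFI peaks (vertical axis) by the number of ChIP tags in the 251 bp peak (horizontal axis), with bars coloured by even and odd tag counts. The bars at 10, 12, 14 and 16 tags (258, 218, 85 and 29 peaks) stand above those at 11, 13 and 15 tags (103, 41 and 12 peaks).

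Nr2f1 itself (chromosome 13, 78188971 to 78198873, mm10) had no peak. The nearest one lay 0.616 Mb away, at 78814468 to 78814718, and held 11 tags. The peak with the highest caller score, 17, lay on chromosome 11 at 88970489 to 88970739, 2024 bp outside the pseudogene 2210409E12Rik and 3321 bp from Coil, which encodes the Cajal body protein coilin. It held 21 tags (95% exact Poisson interval 13 to 32.1) and had a fold over input of 4.07, tied for the lowest in the list, with 5.2 scaled input tags. The second-ranked peak, with 16 tags, lay on chromosome 9 at 3035043 to 3035293, 3501 bp from the microRNA gene Mir101c. Its fold over input was 4.65, with 3.4 scaled input tags. The third, with 19 tags and a fold over input of 7.37, lay on chromosome 11 at 3101352 to 3101602, and the nearest gene was the pseudogene Pisd-ps1 at 22525 bp. It had 2.6 scaled input tags. The first-, second- and third-ranked peaks were thus all among the 41 of 754 peaks with scaled input above its lowest value. Why input was raised at these peaks was not tested, and a nearest gene does not make them binding sites.

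Among the 10 peaks with the highest score, 5 had their centre inside a gene. The peak at Acbd3, which encodes a Golgi protein, lay on chromosome 1 at 180725918 to 180726168 with its centre on an end of the annotated gene, and it held 18 tags (10.7 to 28.5) at a fold over input of 9.69. The peak in Mroh2a (chromosome 1, 88232973 to 88233223) held 16 tags, yet only 4.93 times the density of the 10 kb around it. The peaks in Samd5 (chromosome 10, 9525613 to 9525863) and in the zinc finger gene Zfp978 (chromosome 4, 147239241 to 147239491) held 14 tags each, and the Zfp978 peak stood only 4.72-fold above its surroundings. The fifth lay in the pseudogene Gm13858 (chromosome 6, 34379968 to 34380218) with 13 tags. The remaining peaks of this set had Gm30366 (15 tags, 2.6 scaled input tags, 46041 bp away) and Gm3815 (14 tags, 79793 bp away) as their nearest genes. The tag intervals of these 10 peaks overlapped. Their order followed the caller score rather than the tags, and the score carries no interval, so that order was not tested.

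The second question was which retinal genes lay at the peaks. Few peaks had a listed retinal gene nearest to them, and their number lay within that of random placements. Of 561 genes on 18 lists of retinal cell types, pathways and comparison tissues, 21 were the nearest gene of a peak, and 23 of the 754 peaks (3.05%) had such a gene. Over the 14 lists of retinal cell types and pathways together, 22 peaks had a listed gene, against 20.3 in 10000 random placements of the peaks (95% of placements 12 to 29, ratio 1.08, two-sided permutation p = 0.763). No list passed after Benjamini-Hochberg adjustment over the 18 lists, and 1 list, Notch signalling, had an unadjusted p under 0.05.

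Of the 29 genes of the Notch list, 4 held a peak where 0.766 was the mean of the placements (ratio 5.23, two-sided permutation p = 0.016, adjusted p = 0.288). Maml2, which encodes a Mastermind-like coactivator of the Notch intracellular domain, had the highest of them, with 16 tags (9.15 to 26.0) and a fold over input of 8.61 on chromosome 9 at 13455414 to 13455664. Its relative Maml3 had a peak of 10 tags (chromosome 3, 51715279 to 51715529). Mib1, which encodes the ubiquitin ligase that Notch ligands need for signalling, had 10 tags at 631 bp inside an end of the gene (chromosome 18, 10726131 to 10726381). The fourth gene was the receptor gene Notch2 (chromosome 3, 98020648 to 98020898, 10 tags), named here after its values were seen. With only protein-coding genes considered, the 4 peaks stood against 1.29 in the placements (ratio 3.11, permutation p = 0.085, adjusted p = 0.731). With the 377 higher-scoring peaks alone, 1 peak was counted against 0.379 (permutation p = 0.631). Notch1, Dll1 and Hes1 had no peak assigned, and their nearest peaks lay 0.369, 3.52 and 0.192 Mb away.

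The list of axon guidance and cell adhesion had 6 peaks against 9.37 in the placements (ratio 0.641, permutation p = 0.334, adjusted p = 1). Lrrc4c, which encodes a netrin-G ligand of axons and synapses, held 18 tags (10.7 to 28.5) at a fold over input of 9.69, inside the gene and 430993 bp from its nearer end (chromosome 2, 96749037 to 96749287). The adhesion genes Nlgn1 (chromosome 3, 26122567 to 26122817), Cntn4 (chromosome 6, 106275453 to 106275703) and Cntn1 (chromosome 15, 92099334 to 92099584) each held a peak of 12 tags. So did the guidance genes Unc5b, a netrin receptor gene (chromosome 10, 60792900 to 60793150), and Slit3 (chromosome 11, 35337133 to 35337383). Robo1, Slit1 and Dcc had no peak assigned. When only protein-coding genes were considered, this list had 8 peaks against 19.8 in the placements (ratio 0.403, permutation p = 0.0034, adjusted p = 0.0612).

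The nuclear receptor list had 4 peaks at 2 genes against 2.25 in the placements (ratio 1.78, permutation p = 0.377). Rora, which encodes a retinoid-related orphan receptor needed for cone opsin expression, had a peak of 12 tags where it overlaps the non-coding gene Gm15511 (chromosome 9, 69358455 to 69358705) and another of 10 tags (69203526 to 69203776). Rxrg, a retinoid X receptor gene expressed in cones, had 2 peaks outside the gene on chromosome 1, of 11 tags at 12315 bp (167585922 to 167586172) and of 10 tags at 14776 bp (167583461 to 167583711). These also made up the 2 peaks of the photoreceptor list, against 0.662 in the placements (permutation p = 0.287). The closest relative of COUP-TFI on the list, Nr2f2, had no peak assigned, and its nearest peak, of 10 tags, lay 22203 bp away.

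The list of retinal axes and retinoic acid had 3 peaks against 1.37 in the placements (ratio 2.20, permutation p = 0.312). The ephrin gene Efna5 (chromosome 17, 62818966 to 62819216) and the Eph receptor gene Ephb2 (chromosome 4, 136765266 to 136765516), which act in the retinotectal map and in axon crossing at the midline, held 12 tags each. Foxd1, a transcription factor gene of the temporal retina, had a peak of 10 tags at 11499 bp (chromosome 13, 98342621 to 98342871). Foxd1 was also the only gene among the first 3 members of any list to which a peak was assigned.

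Cell cycle genes had 2 peaks against 0.525 in the placements (permutation p = 0.195): 14 tags at 9812 bp from E2f3 (chromosome 13, 29896638 to 29896888) and 12 tags inside the cyclin gene Ccnd3 (chromosome 17, 47526958 to 47527208). Single peaks fell in Myt1l of the ganglion cell list, with 16 tags (chromosome 12, 29652836 to 29653086), and in Zfhx3 of the amacrine and horizontal cell list, with 15 tags (chromosome 8, 108381036 to 108381286). Their lists had means of 2.21 and 1.06 in the placements. Wnt3, a Wnt ligand gene, held 11 tags at 871 bp inside an end of the gene (chromosome 11, 103817025 to 103817275), against 1.21 peaks of the Wnt list in the placements. The lens crystallin gene Crybb2 held 10 tags at 519 bp inside an end (chromosome 5, 113069473 to 113069723), against 0.243 for the lens list.

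No peak was assigned to the eye field and progenitor list (0.503 in the placements), the optic stalk list (0.369), the pigment epithelium list (0.406), the bipolar and Mueller glia list (0.918) or the Hedgehog, BMP and FGF list (1.03). The same held for vessels and periocular mesenchyme (0.650), blood and microglia (0.181) and ribosomal proteins (0.207). Of the eye field regulators, Pax6 lay 1.29 Mb and Rax 1.64 Mb from their nearest peaks. The homeobox genes Vax2 of the ventral retina and Crx of photoreceptors lay closer, at 47844 bp and 33386 bp. With expected counts under 1 for most of these lists, a count of 0 was within the placements, and a shortage of peaks was not detectable.

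**Figure D2:**
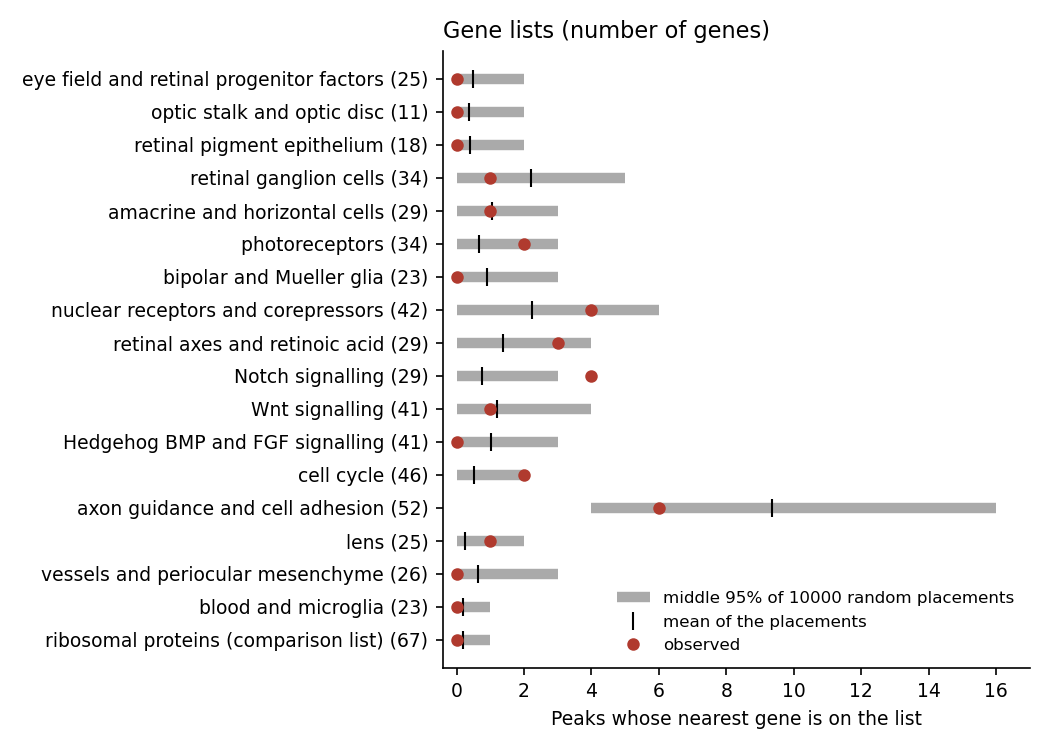
Number of peaks whose nearest gene is on each of the 18 lists (horizontal axis), with the number of listed genes in brackets. Red points are the observed counts, black ticks the means and grey bars the middle 95% of 10000 random placements, and only the Notch list, with 4 peaks, lies outside its bar.

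The third question was how the peaks lay relative to genes. Peaks fell inside genes and close to gene ends more often than placed at random, by a modest margin. In all, 417 of the 754 peaks (55.3%, 95% exact binomial interval 51.7 to 58.9) had their centre inside a gene, against 49.4% in the placements (two-sided permutation p = 0.0016). The 343 peaks inside protein-coding genes made up 45.5% against 41.0% (permutation test, adjusted p = 0.0324 over 4 classes). The 249 peaks farther than 5 kb from any gene made up 33.0% against 40.6% (permutation test, adjusted p = 8.00e-04). The 74 peaks inside other kinds of gene (9.81% against 8.35%) and the 88 within 5 kb outside a gene (11.7% against 9.99%) did not pass, each with an adjusted p of 0.174.

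Peaks also lay near the ends of genes more often than placed at random. Within 5 kb of either end of a gene lay 224 peaks (29.7%) against 179.3 in the placements, a ratio of 1.25 (permutation p = 4.00e-04). Within 1 kb lay 77 peaks against 47.9 (ratio 1.61, permutation p = 2.00e-04, the smallest that the placements can give), and for protein-coding genes alone 43 against 23.5 (ratio 1.83, permutation p = 8.00e-04). Within 50 kb lay 639 peaks against 571.8 (ratio 1.12, permutation p = 2.00e-04), and the ratios at the 3 distances were not tested against each other. Starts and stops of genes were not told apart, since strand was not used here. Among the 377 higher-scoring peaks, the share inside genes was 53.6% and no longer passed (permutation p = 0.102). Most of these peaks shared the lowest score and were chosen by their tags and local fold. The placements were not matched on base composition or mappable sequence.

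The fourth question was how the peaks spread over the chromosomes. The X chromosome stood out: it carried 9 peaks, 1.19% of the total (0.547 to 2.25), against 38.3 from its share of annotated genes (ratio 0.235, two-sided exact binomial test, adjusted p = 3.36e-07 over 20 chromosomes). Those 9 peaks held 10 to 13 tags, and among the genes they fell in were Atp2b3, a plasma membrane calcium pump gene, and Reps2, both named after their values were seen. By length in place of gene number, 49.2 peaks would lie on X (ratio 0.183, exact binomial test, adjusted p = 3.18e-11). Chromosome 7 had 32 peaks against 63.6 by gene number (ratio 0.503, exact binomial test, adjusted p = 7.66e-05), but against 41.7 by length (ratio 0.767, adjusted p = 0.422). Over the 19 autosomes, the counts did not depart from their lengths (chi-square 20.4, p = 0.317 from 10000 random draws) and did depart from their gene numbers (chi-square 38.8, p = 0.0024).

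**Figure D3:**
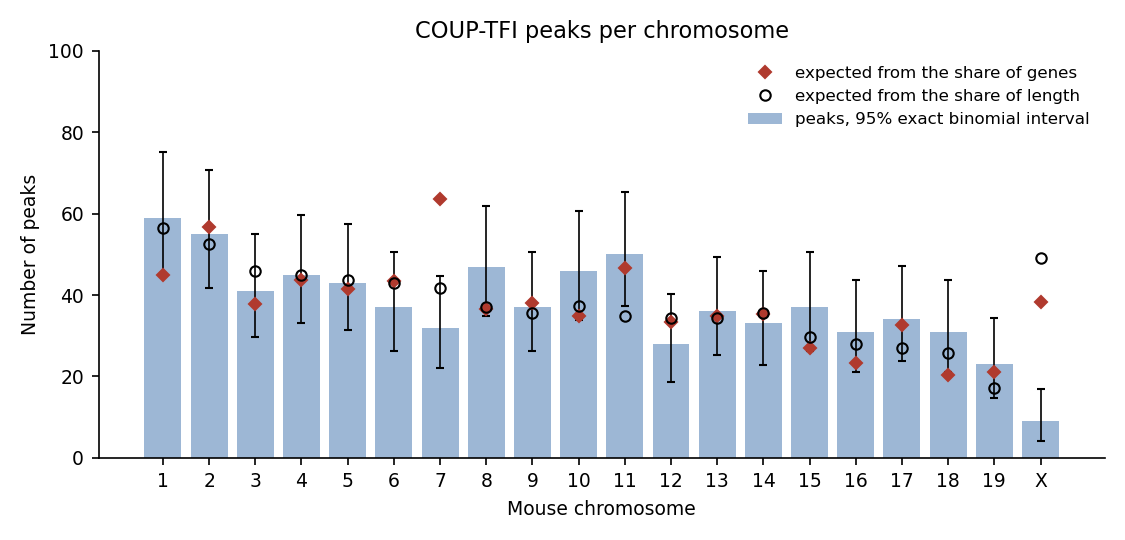
Number of COUP-TFI peaks on each chromosome (bars, with 95% exact binomial intervals), with the number that the share of genes (red diamonds) and the share of length (open circles) would give. The X chromosome, with 9 peaks, lies below both marks, and chromosome 7, with 32 peaks, lies below the mark for genes while its interval holds the mark for length.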

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

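The number of peaks fell from 754 to 377 for the higher-scoring peaks and to 31 for peaks with at least 2 times the lowest fold over input, both by construction. The share inside genes was 53.6% for the higher-scoring peaks, most of them tied at the lowest score. It no longer passed (permutation p = 0.102), with fewer peaks tested. Alternatives chosen after seeing the data were 2 of the expected shares per chromosome, the merging of peaks within 10 kb for genes and lists, and the removal of peaks with input above its lowest value. By the share of protein-coding genes, 4 chromosomes passed, and by length 1, against 2 by all genes, and X was among them each time. The excess near gene ends passed under each of its alternatives that was run.

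No list passed under any of the 6 alternatives of the list test. Of 108 list values, 93 kept their direction and 15 did not, all on small counts, and the cause was not tested. Part of the 93 was fixed in advance, since a list without a peak could gain a peak only with the nearest protein-coding gene. With the nearest protein-coding gene, the 14 lists together had a ratio of 0.962, and the optic stalk list had 1.18, retinal axes 0.817, Wnt 2.15, Hedgehog, BMP and FGF 1.44 and ribosomal proteins 1.03. With the higher-scoring peaks, amacrine and horizontal cells had 1.90, photoreceptors 0, nuclear receptors 0.850, Wnt 1.65 and lens 0. Within 10 kb, amacrine and horizontal cells had 1.21, photoreceptors 0 and nuclear receptors 0.977. With each gene counted once, amacrine and horizontal cells had 1.02 and nuclear receptors 0.941. Of 30 alternatives fixed before the data were examined, 13 that need sequence or strand were not run, nor was the share of assembled bases. No paired analysis was possible because each group has 1 library.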

Other observations

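The lists were fixed before the data were examined, but the plan of tests did not name the count over the 14 lists together. The other tests in this part, on crowding, the number of peaks and the X chromosome, and the genes named here were chosen after the results were seen. With non-coding genes and pseudogenes set aside, further retinal regulators became the nearest protein-coding gene of a peak. The closest were Irx2, an Iroquois homeobox gene, with 14 tags at 1.64 kb, Smad7, an inhibitor of TGF-beta signalling, with 12 tags at 3.91 kb, and Nr2e1, the orphan nuclear receptor gene of retinal progenitors also called Tlx, with 12 tags at 4.48 kb. At 19.8 kb from Rspo1, an enhancer of Wnt signalling, lay a peak of 10 tags, and at 24.2 kb from Tcf7l2, a Wnt effector gene, a peak of 14 tags. Prdm1, which favours photoreceptors over bipolar cells, was the nearest protein-coding gene of 2 peaks, of 15 tags at 95.6 kb and of 12 tags at 208 kb. Over the 14 lists, 45 peaks had a listed gene in this way, against 46.8 in the placements, so these genes were no more frequent than placed at random.

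The most crowded stretch of the genome was chromosome 4 from 147000001 to 148000000, a cluster of zinc finger genes, with 8 peaks of 10 to 14 tags. Zfp978 was the nearest gene of 4 of them, and the nearest genes of the others were Gm13161, Gm13141, Zfp984 and Vmn2r-ps20. In 10000 placements the fullest stretch of 1 Mb held 7 peaks at most (one-sided permutation p = 1e-04, the smallest one-sided value that they can give). With peaks within 10 kb counted as 1 region, it held 6, a number that the fullest stretch also reached in some placements (one-sided permutation p = 0.0024). These 8 peaks stood 4.32 to 10.8 times above their surroundings, against a median of 11.65 over all peaks. For the 473 peaks at the lower bound of the local density, that fold follows the ChIP tags alone. Scaled input among the 8 peaks reached 3.4 tags, where most peaks of the list stood at 1.9. The placements were not matched on mappable sequence, so clustered binding cannot be told apart from uneven mapping here.

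On the number of peaks, the first pattern, tags placed singly and evenly at random gave 1.4 regions of at least 10 tags, against 754 listed. The caller's false discovery rate of 0.001 had set that minimum of 10 tags, so a number this low was largely fixed in advance. It cannot decide whether chance was the cause. Tag counts were mostly even, as they would be if both ends of a fragment were counted as tags: 71.5% of the 246 counts recovered for the surrounding 10 kb were even (exact binomial interval 65.5 to 77.1; counts whole within 0.05 tags, of 281 above their lower bound), and 68.0% of the peaks of 11 to 16 tags (63.7 to 72.2). If unpaired tags follow a Poisson distribution, the former puts their share at 0.963% (0.699 to 1.35) and the latter at 4.09% (3.26 to 5.21), and why these differ was not tested. Chance alone then gave 1763.7 regions with 94.79% of tags in pairs and 2204.5 (SD 57.5 over 10 simulations) with all, against 1283 before the caller's filters (with 50% in pairs it gave 279.4, but counts would then be even in 50%, below those seen), so that an unknown part of the list may be chance pile-ups of about 5 fragments. These cannot be told apart from binding here, because the simulation assumes an even genome and sets both tags of a pair on 1 position, so that no region edge splits a pair. It used the mean density of 0.003225 tags per bp. Over the caller's genome size of 2000000000 bp, this gives fewer tags than the library's 7371400, so the simulated numbers may be too low. With all tags in pairs it gave 175 regions of 12 or more tags, where 393 listed peaks held as many. By the caller score, which is not defined further, 87 listed peaks reached 12 or more.

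The shortage of peaks on the X chromosome is the second pattern. A candidate explanation is the single X of male embryos in a pool of both sexes, and it cannot be told apart from other causes here, because its prediction depends on how peaks arise. If peaks were chance pile-ups of 5 independent fragments, a density of 0.75 would give a ratio of 0.237, inside the interval of the observed ratio by length, 0.183 (0.0839 to 0.346). With 10 independent tags it would give 0.0563, and for peaks that scale with the density alone 0.75, both outside the interval. The sex of the embryos was not given in the sources used here, and neither mappability of the X chromosome nor a biological explanation was tested.

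The excess of peaks inside genes is the third. Base composition and mappable sequence, which differ between genes and the space between them, may account for the excess of 5.92 percentage points, and this cannot be told apart from binding without the genome sequence. Easier recovery of open chromatin was not tested, and no biological explanation was tested.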
